A study of Mus musculus with 5 samples.

How the data were processed

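Chromatin accessibility was measured by single-cell ATAC-seq, in which a transposase cuts open DNA in single nuclei, in 5 libraries of mouse duodenal crypt cells. Per the labels, the cells came from mice in which tamoxifen activates a Cre recombinase driven by Atoh1, a transcription factor of secretory cells, and the red reporter TOM marks the cells in which Cre acted. Mice received 2 doses of tamoxifen at 1 mg/mL, 24 h apart, and crypts were taken 12 h after the last dose. Crypts were released with EDTA, dead cells were excluded with DAPI and TOM-positive cells were sorted, per the labels' protocols, before libraries were made with version 1.1 of the 10x single-cell ATAC kit. The WT group (2 libraries) carried the reporter alone and the APC-KO group (3 libraries) also carried floxed Apc alleles. The labels number the libraries as replicates and nothing says that they came from separate animals. No p-value here thus draws on more than these libraries, whose spread may be technical.

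The authors deposited, for each library, the peaks, the cell barcodes and a matrix of whole-number counts per peak and barcode, made with Cell Ranger ATAC 2.0.0 per the file headers. Cell Ranger 2.0.0 and the mm10 build are also named in the submitters' processing notes. The aligner settings, the peak-calling settings and the filters on cells are not given in the sources used here. Counts of 2 made up 65.8% to 78.9% of the nonzero values and counts of 1 made up 10.4% to 19.5%, as when both ends of a fragment are counted, so a value is best read as cut sites and the counting error is larger than its square root. The peaks were called in each library separately. A pair of deposited metadata files, one for each genotype, name the library and the cell type of each cell that the authors kept, and every listed barcode was found in its library's matrix. The 8 cell type names (EEC, ENTERO-PRO, GOBLET, GP, ISC, PANETH, SEC-PRO and TUFT) were used as the authors wrote them. How cells were clustered and named, and how doublets were treated, is not given in the sources used here, and no doublet caller was run.

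Peaks that overlapped by at least 1 bp across libraries were merged into 162574 regions. The tests used the 90449 regions on standard chromosomes that held a peak in all 5 libraries, since a library without a peak in a region has no count there, whatever its signal. These regions held 93.5% to 95.9% of the counts of each library's kept cells. A library's value is the sum of its counts over its own peaks in the region and over the cells kept by the authors, so it also moves with the width of the peak called. Sequences outside the standard chromosomes held 0.180% to 0.228% of the counts and were left out of the tests. Gene positions came from a RefSeq gene table of assembly GRCm38.p6, which is the mm10 build, with 49943 genes on standard chromosomes. The table was used without strand, so regions within 1 kb of either end of a gene, called gene-end regions here, replaced the promoters that had been planned. A total of 21540 genes had one. Genes that share an end region share its counts and cannot be told apart. A wider sum over the gene body and 2 kb on either side (26499 genes) was an alternative. No genome sequence was used, so neither motif content nor a correction for GC content was run.

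Library sums were tested with edgeR 4.0.16 (TMM factors, filterByExpr, glmQLFit and glmQLFTest, two-sided) with the group as the single term and Benjamini-Hochberg adjustment over all regions or genes tested. Calls are at an adjusted p under 0.05, and every adjusted p of a gene or region is from this test unless another is named. Log2 fold changes are APC-KO minus WT, with standard errors from the same fit, and levels are counts scaled to library size (CPM) given as mean ± SD over libraries, 2 for WT and 3 for APC-KO. The TMM factors lay between 0.957 and 1.04. The biological coefficient of variation was 0.136 for regions and 0.0750 for genes. Prior degrees of freedom weigh the spread shared by all features against a feature's own. In all cells they were 9.00 for regions and 474 for genes. A gene's p-value there rests mostly on the shared spread and little on the spread of that gene between libraries. Gene lists were tested with camera of limma 3.58.1, which asks whether a list moves more than the other genes, at a preset correlation of 0.01 between genes. The adjustment was over the 14 lists, or over the 98 tests of 14 lists in 7 classes. None of the 3 list calls in all cells and none of the 9 in classes held with an estimated correlation in camera, and those p-values stand beside the calls. For fry, of the same package, the p-value asks whether a list's genes move on balance one way, its mixed p-value asks whether they change in either direction, and neither compares the list with other genes. Cell type shares were compared by an exact two-sided permutation test over the 10 splits of 5 libraries into 2 and 3, whose smallest p is 0.1.

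Within a class, the same tests were run on counts summed over the cells of that class, for the 7 classes with at least 50 cells in every library (ENTERO-PRO, with 24 cells in its smallest library, was left out). Classes were compared with each other in a fit with the library as a block, over 21 pairs, and the difference of the genotype effect between classes was tested as an interaction. As the class names may have been given from these same counts, p-values between classes are too small. Peak sets were compared with bedtools 2.31.1. Other tools were R 4.3.3, data.table (version 1.17.8), DESeq2 1.42.0 (alternative), Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

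The genes named are Apc and Atoh1, the 10 largest rises and 10 largest falls among called genes whose libraries did not overlap between genotypes and whose mean level was at or above the median, and up to 4 members per list with the smallest adjusted p. Gene models without a known gene's name were left out where their end regions are the same as those of a named gene. Regions named are the 5 largest rises and 5 largest falls by the same rule, the 3 with the highest mean count among the peaks of one genotype alone, and, between classes, the 5 list members with the largest difference each way. Some list members called within a class are named too, chosen after their values were seen. A gene that the rule picks is not reported here. The 14 lists cover Wnt targets, stem cells, Paneth cells, goblet cells, secretory progenitors, enteroendocrine cells, tuft cells, enterocytes, proliferation, BMP targets, Notch, fetal or regenerative genes, immune cells, and stromal or endothelial cells. Lists, tests, naming rule and most alternatives were fixed before the data were examined.

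The tests of regions and genes in all cells, of regions within a class and of regions between classes were run on simulated data. In these, 200 regions or genes were changed by known amounts. The changed ones were drawn from those with summed counts at or above the median, so recovery at lower counts was not measured. Interactions, genes within classes, shares and peak sets were not simulated. For regions in all cells (90449 tested) 48% of 1.5-fold and 96% of 2-fold changes were recovered, with 10.6% of calls false. For genes in all cells (21540 tested) 100% of both were recovered, with 4.76% of calls false. For regions in PANETH (89746 tested) 15% and 74% were recovered with 2.20% of calls false, and for PANETH against GOBLET (87263 tested) 55% and 96% with 9.04% false. A raised list was called at an adjusted p of 2.87e-27 and 0 of the 13 other lists were called by camera, among them the Wnt list, which shares 6 members with it (adjusted p = 0.0757). The simulated genes were drawn independently, so this does not measure false list calls where genes are correlated. In the data the estimated correlation was 0.31 for the Paneth list, 0.21 for the enteroendocrine list and 0.06 for the tuft list. Alternatives were DESeq2, a replicate block, all barcodes, cells with a count in a region in place of counts, thinning to the total of the smallest library, scaling by total counts, gene bodies, regions with a peak in at least 2 libraries, other peak overlaps, equal numbers of cells and leaving out each library. Added after seeing the data were regions of stable peak width, an equal make-up of cell types, the larger gene end and 100 cells per class. So were removal of chromosome 18 and gene ends from regions with a peak in at least 2 libraries. The same holds for the alternatives for class lists, class genes and interactions. An equal make-up took the same number of cells of each class from every library and did not make the counts per cell equal.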

Results

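Open chromatin was profiled in single TOM-positive cells sorted from duodenal crypts of WT mice (2 libraries) and of mice in which Cre under Atoh1 control also acts on floxed Apc alleles (APC-KO, 3 libraries). Apc restrains Wnt signalling by promoting the destruction of beta-catenin, and Atoh1 marks the secretory cells of the intestine. The comparison asks how accessibility in these cells differs when Apc is targeted. The authors kept 10049 and 5058 cells in WT replicates 1 and 2, and 7828, 10637 and 7768 cells in APC-KO replicates 1, 2 and 3. These cells held 107728639 and 79667552 counts in the WT libraries and 110432359, 119603903 and 95205458 counts in the APC-KO libraries. Median counts per kept cell were 9449 and 13230 in WT and 12200.5, 9874 and 10513 in APC-KO. Correlations of log2 CPM over regions between libraries, which are across regions and not across independent samples, ranged from 0.966 to 0.993, and the highest was between APC-KO replicates 2 and 3.

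The targeted gene Apc did not differ in accessibility between the genotypes. Its gene end (mm10 chromosome 18, gene from 34220297 to 34322190) was at 46.2 ± 4.72 CPM in WT (SD, n = 2) and 52.1 ± 2.66 CPM in APC-KO (SD, n = 3). The log2 fold change was 0.17 (SE 0.10, edgeR adjusted p = 0.325). Atoh1, the gene that drives Cre and a regulator of secretory fate (chromosome 6, 64729125 to 64731245), was at 84.5 ± 2.18 and 87.4 ± 9.80 CPM, a log2 fold change of 0.05 (SE 0.11, adjusted p = 0.810). Of the 11 regions over Apc, edgeR called 0, with 1 higher at an unadjusted p under 0.05 and 0 called by DESeq2, and their log2 fold changes lay between −0.21 and 0.29. Of the 2 regions over Atoh1, edgeR called 0, with 0 at an unadjusted p under 0.05 and 0 called by DESeq2, at 0.02 and 0.08. The labels do not say which exons of Apc are floxed, and accessibility outside deleted exons says nothing about the deletion, so these values do not check the genotype.

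TUFT cells made up 6.18% ± 0.904 of the kept cells in WT (SD, n = 2) and 1.69% ± 0.342 in APC-KO (SD, n = 3), with no overlap between the genotypes (exact permutation p = 0.1, the smallest that 10 splits allow). SEC-PRO cells made up 20.7% ± 1.53 in WT and 23.9% ± 1.12 in APC-KO, also without overlap (exact p = 0.2). PANETH cells were 15.2% ± 1.76 and 22.2% ± 5.13 (exact p = 0.3), and EEC cells 7.55% ± 1.91 and 4.58% ± 1.56 (exact p = 0.3). GOBLET cells were 10.2% ± 3.91 and 11.6% ± 4.19 (exact p = 0.6), and GP cells 21.1% ± 4.57 and 22.8% ± 9.17 (exact p = 1). ISC cells were 17.8% ± 10.3 and 12.5% ± 0.317 (exact p = 0.5), and ENTERO-PRO cells 1.29% ± 0.792 and 0.704% ± 0.359 (exact p = 0.5). Adjusted over the 8 classes, the p-values were 0.6 or higher, and the design cannot reach 0.05. Without WT replicate 1 the difference turned to −1.35 points for GOBLET, −1.60 points for GP and 2.05 points for ISC. Without APC-KO replicate 1 it turned to −3.66 points for GP. It also moved from −2.96 to −1.61 points for EEC without WT replicate 2, and from 3.16 to 2.08 points for SEC-PRO without WT replicate 1. For ENTERO-PRO it went from −0.59 to −0.028 and −1.15 points without WT replicates 1 and 2 and to −0.39 without APC-KO replicate 1. Without WT replicate 2 it was 4.18 points for GOBLET, 4.87 for GP and −12.5 for ISC. For GOBLET it went from 1.41 to 3.83, 0.19 and 0.21 points without APC-KO replicates 1, 2 and 3, and for GP from 1.63 to 4.40 and 4.16 points without APC-KO replicates 2 and 3. The sort for TOM and the authors' filters on cells can set these shares. The names are the authors', and in the class named ISC 15 of 21 enterocyte genes and 5 of 15 stem genes were higher than in the other classes.

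**Figure D1:**
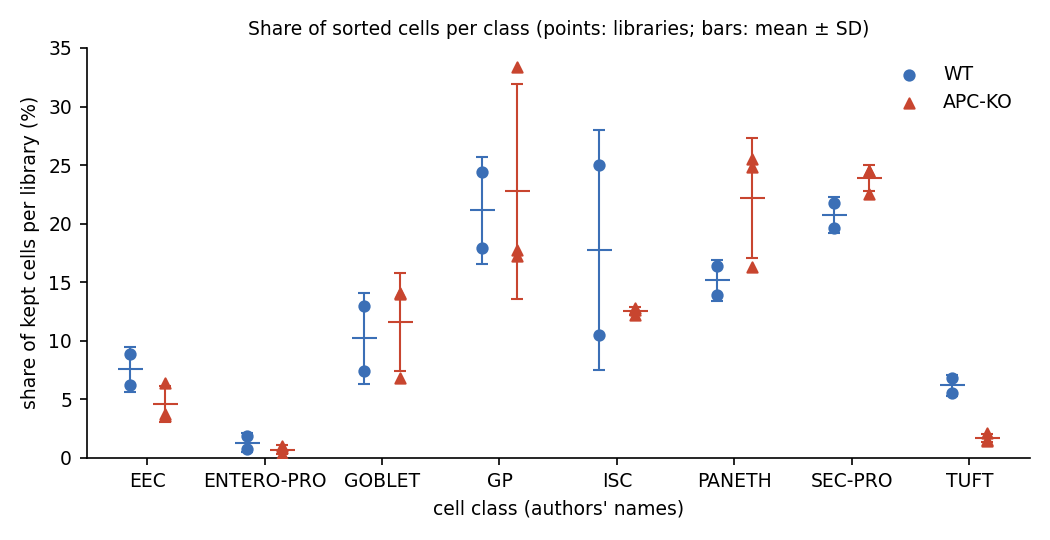
Share of kept cells (percent, vertical axis) of each of the 8 classes named by the authors, with a point per library (circles WT, triangles APC-KO) and the mean and SD of each genotype as lines. TUFT is the class with the clearest gap, at 6.18% in WT and 1.69% in APC-KO.

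Across all kept cells, 956 regions were more accessible and 1021 less accessible in APC-KO among 90449 tested (edgeR, adjusted p under 0.05), with 213 of the higher and 318 of the lower regions changed at least 2-fold. The largest rise was at chromosome 6, 115823472 to 115824564, inside Efcab12, which went from 1.2 ± 0.279 CPM in WT to 9.39 ± 0.591 CPM in APC-KO (log2 fold change 2.98, SE 0.18, adjusted p = 7.16e-05). Other large rises were at chromosome 18, 23414877 to 23415796, inside Dtna (2.46), and at chromosome 2, 144291519 to 144292472, 10291 bp from Mgme1 (2.07). They were followed by chromosome 18, 32054693 to 32055617, 11708 bp from Iws1 (2.00), and chromosome 9, 70301204 to 70302229, inside Myo1e (1.79). Of the 5 rises, 2 lay on chromosome 18, which carries Apc, and 4.01% of the 674 regions in the 20 Mb around Apc were called, against 2.19% of all regions. The largest fall was at chromosome 8, 20557266 to 20558263, 5039 bp from Gm40469, from 16.7 ± 3.02 to 1.92 ± 0.396 CPM (log2 fold change −3.12, SE 0.18, adjusted p = 6.40e-05). The next 4 falls lay together near the end of chromosome Y, between 90800240 and 90808074, with log2 fold changes from −1.98 to −1.91. The sex of the animals is not given in the sources used here. Near genes, 6.90% of the higher and 4.90% of the lower regions were within 1 kb of a gene end, against 15.5% of all tested regions. Of the 531 regions that changed at least 2-fold, 16.6% had another such region of the same direction within 100 kb. All called regions had libraries that did not overlap between the genotypes, as did 36.7% of all tested regions, where chance gives 20%. The region near Mgme1 lost its call without WT replicate 2 (adjusted p = 0.0598, range over its alternatives 3.54e-18 to 0.182). The region at chromosome Y, 90807255 to 90808074, lost it without WT replicate 1 (0.0716, range 1.99e-23 to 0.257). When regions with a peak in at least 2 libraries were tested, the regions inside Dtna and Myo1e lost their calls (0.0766 and 0.151), as did the 4 on chromosome Y (0.190 to 0.257) and the region near Mgme1 (0.182).

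**Figure D2:**
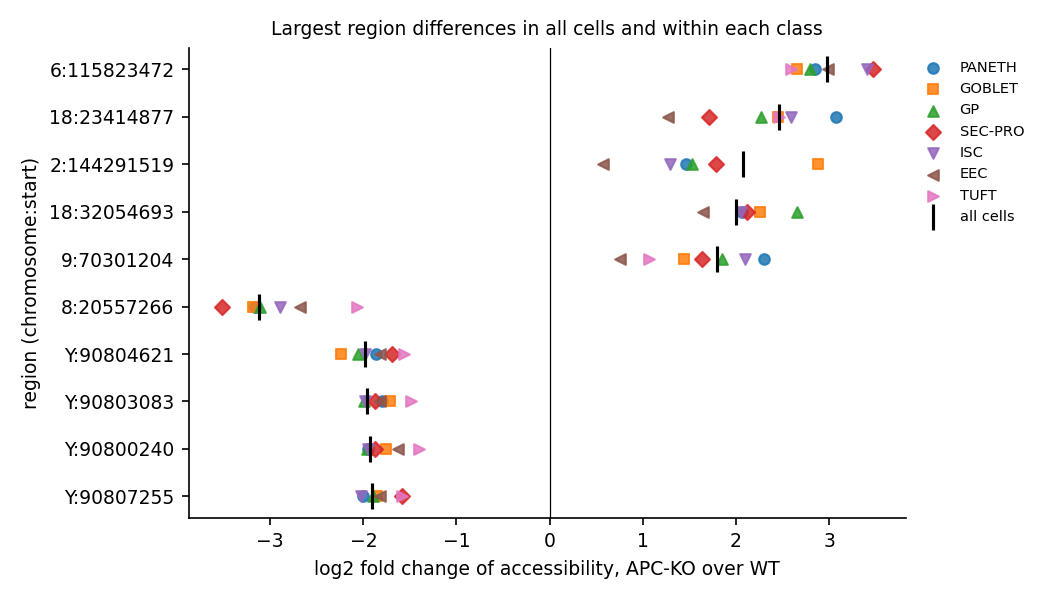
Log2 fold change in accessibility (APC-KO over WT, horizontal axis) of the 5 regions with the largest rises and the 5 with the largest falls, with a black bar for all cells and a coloured mark for each class with a value. The region inside Efcab12 is at 2.98 and the region near Gm40469 at −3.12 in all cells.

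The number of called regions moved with single libraries. It was 360 higher and 854 lower without WT replicate 1 and 185 and 178 without WT replicate 2. It was 2246 and 2511 without APC-KO replicate 1, 200 and 144 without APC-KO replicate 2, and 526 and 390 without APC-KO replicate 3. The share of higher regions among the called was 48.4%. It was 38.4% with an equal make-up of cell types (1062 higher, 1705 lower). It was 85.7% when regions with a peak in at least 2 libraries were tested with 0 where a library had no peak (737 higher, 123 lower). Of these, only 49 higher and 27 lower regions were among the 956 and 1021 reported calls.

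At gene ends, of the 14 measured members of the Paneth list 6 rose, none fell and 8 were not called, with a list median log2 fold change of 0.29. Clps, which encodes a cofactor of pancreatic lipase, went from 30.4 ± 1.43 to 45.1 ± 5.37 CPM (log2 fold change 0.57, SE 0.10, adjusted p = 2.12e-06). The defensin gene Defa24 rose from 3.56 ± 1.00 to 7.07 ± 2.22 CPM (0.99, SE 0.18, adjusted p = 9.07e-06), a value that is uncertain because defensin genes are near-identical copies. The stress-response gene Nupr1 rose by 0.53 (adjusted p = 2.41e-05) and Guca2b, which encodes uroguanylin, by 0.63 (adjusted p = 0.00244). The list was called up relative to all genes by camera (adjusted p = 0.00174), but not otherwise (adjusted p = 0.879 with an estimated correlation), and fry gave p = 0.0729 for a shift on balance one way. PANETH cells were 22.2% of cells in APC-KO and 15.2% in WT. With an equal make-up of cell types Clps was at 0.25 (adjusted p = 0.0972, range over its alternatives 3.86e-10 to 0.278), Nupr1 at 0.22 (0.173, range 7.85e-07 to 0.546), Defa24 at 0.69 and still called (0.00844, range 3.94e-12 to 0.467), and the list at an adjusted p of 0.718 (range 2.63e-07 to 0.718). The list call was also lost without WT replicate 1 (adjusted p = 0.0515). Guca2b lost its call without WT replicate 2, APC-KO replicate 2 or APC-KO replicate 3 (adjusted p = 0.388, 0.145 and 0.0703, range over its alternatives 1.54e-06 to 0.445), and with an equal make-up it was at 0.35 (0.173).

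Of 22 measured enteroendocrine genes 2 fell, none rose and 20 were not called, with a median of −0.09. Isl1, a transcription factor of endocrine cells, went from 11.8 ± 0.541 to 8.28 ± 0.183 CPM (−0.52, adjusted p = 0.00975), and the endocrine factor gene Pax6 from 7.24 to 5.06 CPM (−0.52, adjusted p = 0.0402). Neurod1 was at −0.45 and did not pass. The list was called down (adjusted p = 4.17e-05), but not with an estimated correlation (adjusted p = 0.808), and fry gave p = 0.112. With an equal make-up of cell types Isl1 and Pax6 were both at −0.35 (adjusted p = 0.117 and 0.193) and Neurod1 was at −0.22, while the list stayed called down (adjusted p = 3.69e-04, and 0.985 with an estimated correlation). Of 12 measured tuft genes 2 fell, none rose and 10 were not called, with a median of −0.12. Alox5ap, which encodes a protein of leukotriene synthesis, went from 1.89 ± 0.121 to 0.886 ± 0.190 CPM (−1.09, SE 0.25, adjusted p = 0.00124) and lies in a run of 3 regions that were lower in APC-KO. Avil, which encodes advillin, was at −0.62 (adjusted p = 0.0222). The tuft list was called down (adjusted p = 9.11e-05), but not with an estimated correlation (adjusted p = 0.539), and fry gave p = 0.0145. TUFT and EEC cells had lower mean shares in APC-KO. With an equal make-up of cell types the tuft list was at an adjusted p of 0.0746 (range over its alternatives 1.34e-05 to 0.0746), and its median less that of all genes went from −0.21 to −0.15. There Alox5ap kept its call (−0.91, adjusted p = 0.0362) and Avil lost it (−0.44, adjusted p = 0.144). Alox5ap lost its call without APC-KO replicate 2 (adjusted p = 0.0605, range over its alternatives 1.01e-04 to 0.533). Isl1 lost it without WT replicate 1, APC-KO replicate 2 or APC-KO replicate 3 (0.0658, 0.134 and 0.0595, range 2.43e-04 to 0.203). Pax6 lost it without any of WT replicates 1 and 2 and APC-KO replicates 2 and 3 (0.136, 0.0733, 0.420 and 0.145, range 0.00520 to 0.748). Avil lost it without WT replicate 2, APC-KO replicate 2 or APC-KO replicate 3 (0.163, 0.0795 and 0.112, range 0.00750 to 0.353), and over the gene body it was at −0.36 (0.151).

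**Figure D3:**
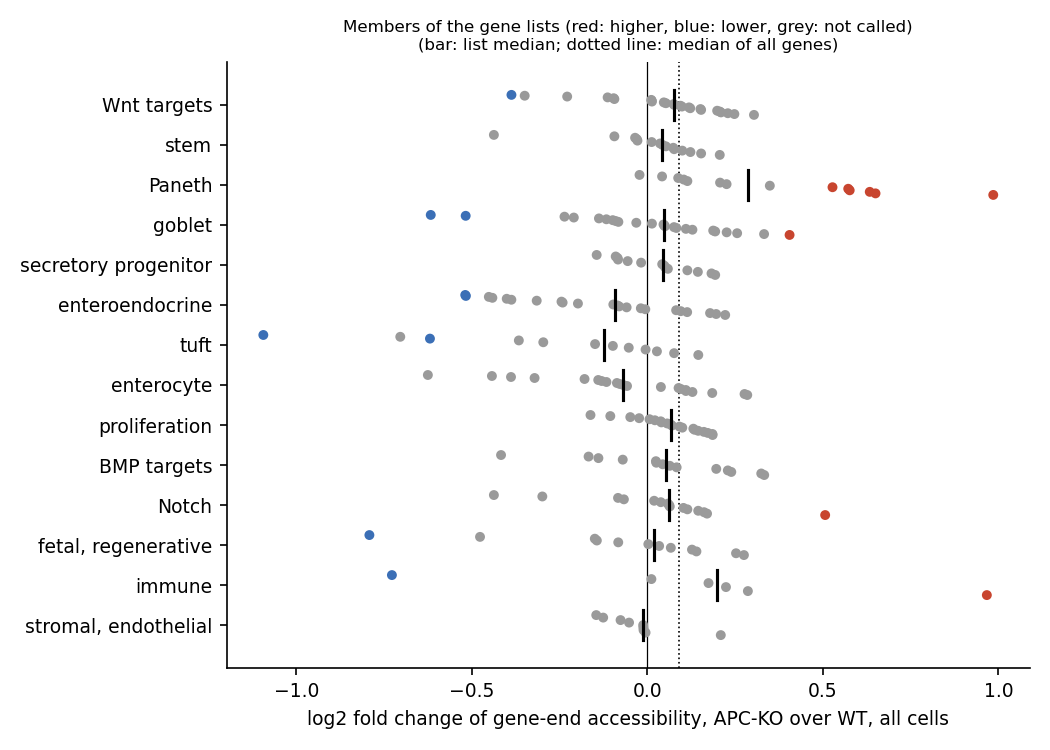
Log2 fold change at gene ends (APC-KO over WT, horizontal axis) of the members of each of the 14 gene lists in all cells, with called members in red (higher) and blue (lower) and a bar for each list's median. The Paneth list has a median of 0.29, the enteroendocrine list −0.09 and the tuft list −0.12, and the dotted line marks 0.09, the median of all genes.

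Targets of Wnt signalling did not move as a group. Of 25 measured targets 1 fell and 24 were not called: Wnt6 was at −0.39 (adjusted p = 0.0394), while the stem cell receptor Lgr5 was at 0.21 (adjusted p = 0.232), Bambi at 0.23 and Prox1 at −0.23. The list had a median of 0.08 and an adjusted p of 0.743. Wnt6 lost its call without WT replicate 1, APC-KO replicate 2 or APC-KO replicate 3 (adjusted p = 0.319, 0.297 and 0.181, range over its alternatives 0.00351 to 0.454). It was at −0.12 over the gene body (0.427) and at −0.18 with an equal make-up of cell types (0.353). None of 15 stem cell genes was called by edgeR, with 1 higher and 1 lower at an unadjusted p under 0.05 and 1 lower by DESeq2. Olfm4, a stem cell marker, was at −0.44 (adjusted p = 0.0610; list adjusted p = 0.740). Of 24 goblet genes, Clca1, a marker of goblet cells, fell to 9.09 ± 1.70 CPM, 0.652 times the WT level (−0.62, adjusted p = 6.28e-04), and Klk1 fell from 14.7 to 10.2 CPM (−0.52, adjusted p = 0.00451). Guca2a, which encodes guanylin, rose (0.41, adjusted p = 0.0316). The other 21 were not called, and the list was at an adjusted p of 0.564 with a median of 0.047. In an equal make-up of cell types its median was −0.071, 4 members were lower and the list was called down (adjusted p = 3.69e-04, but 0.985 with an estimated correlation). Clca1 lost its call without WT replicate 2 (adjusted p = 0.425, range over its alternatives 6.92e-06 to 0.467), and over the gene body it was at −0.17 (0.347). Klk1 lost it without WT replicate 1 or APC-KO replicate 2 (0.158 and 0.0671, range 1.72e-04 to 0.355). Guca2a lost it without WT replicate 2, APC-KO replicate 2 or APC-KO replicate 3 (0.278, 0.419 and 0.186, range 0.00279 to 0.471), and with an equal make-up of cell types it was at 0.21 (0.290).

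Among the other lists, Heyl, a Notch target, rose (0.51, SE 0.12, adjusted p = 0.00284) as the single called gene of 15 in the Notch list (list adjusted p = 0.743). It lost its call without WT replicate 2 or APC-KO replicate 2 (adjusted p = 0.513 and 0.0734, range over its alternatives 3.11e-05 to 0.513), and with an equal make-up of cell types it was at 0.36 (0.0637). Ly6a, a marker of regenerating epithelium, was the single called gene of 12 in the fetal or regenerative list (−0.79, adjusted p = 9.48e-04; list adjusted p = 0.740). It stood at 6.62 ± 4.22 CPM in WT and reversed to 0.054 without WT replicate 2 (adjusted p = 0.999, range 3.73e-09 to 0.999). Among 6 immune genes, Itgam, which encodes an integrin of myeloid cells, rose from 12.1 ± 1.86 to 23.6 ± 4.04 CPM (0.97, SE 0.11, adjusted p = 5.42e-13). The Itgam gene end was also higher in GP and SEC-PRO than in the mean of the other classes (log2 0.89 and 0.56). Its rise need not come from myeloid cells. The B cell gene Cd79b fell (−0.73, adjusted p = 0.00542; list adjusted p = 0.740). Cd79b lost its call without WT replicate 2 or APC-KO replicate 2 (0.111 and 0.0787, range 0.00128 to 0.242), and with an equal make-up it was at −0.55 (0.0646). No member was called by edgeR among 14 secretory progenitor genes (list adjusted p = 0.740), 21 enterocyte genes (0.106), 20 proliferation genes (0.783), 14 BMP targets (0.950) or 9 stromal or endothelial genes (0.564). At an unadjusted p under 0.05 these held 2 higher and 4 lower enterocyte genes and 4 higher and 1 lower BMP targets. DESeq2 called 1 lower enterocyte and 1 lower proliferation gene. Without WT replicate 2 the enterocyte list was called down (adjusted p = 7.25e-04, range over its alternatives 7.25e-04 to 0.837), but not with an estimated correlation (0.599).

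Adjusted over the list alone, the counts were 6 higher for Paneth, 4 lower for enteroendocrine, 3 lower for tuft, 1 lower for Wnt targets, and 1 lower for stem. They were 1 higher and 2 lower for goblet, 1 higher and 2 lower for Notch, 2 higher and 1 lower for fetal or regenerative, and 1 higher and 1 lower for immune genes, and none for the other lists. The median of all genes was 0.09 with TMM scaling, so the Wnt, stem, goblet, secretory progenitor and Notch lists had medians above 0 and were placed below other genes by camera. The fetal or regenerative list had a median of 0.02 and a mean of −0.06.

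Over all genes, 487 gene ends were higher and 442 lower in APC-KO of 21540 tested, of which 457 and 402 had no overlap between genotypes (37.2% of all genes, where chance gives 20%). Among genes at or above the median level, the largest rise of a gene with a known product was Trrap, which encodes a scaffold of histone acetyltransferase complexes (chromosome 5, 144767737 to 144859778), from 26.5 ± 1.40 to 50.2 ± 3.26 CPM (log2 fold change 0.92, SE 0.10, adjusted p = 3.43e-16). Cldn4, which encodes a tight junction claudin, rose from 34.1 ± 1.42 to 53.3 ± 4.93 CPM (0.64, adjusted p = 1.04e-07), and Dnajb5, which encodes a chaperone partner, by 0.61. Fnbp4 rose by 0.62 and Pxn, which encodes the adhesion protein paxillin, by 0.59. One of the 2 end regions of Pxn is also that of the pseudogene Gm13836, which was at 0.78, so these are not separate rises. Over the gene body Pxn was at 0.18 (adjusted p = 0.185, range over its alternatives 6.15e-12 to 0.185) and Gm13836 at 0.27 (0.0711, range 3.05e-12 to 0.0752). Ugp2, which encodes an enzyme that makes UDP-glucose, rose by 0.57, and Zfp78 by 0.57. The pseudogene Gm10060 rose by 1.12 (91.3 ± 4.33 to 198 ± 6.29 CPM), and the pseudogene Gm52169 by 0.93. The largest falls at or above the median level were at the Ugt1a locus, a cluster of genes for enzymes that conjugate glucuronic acid. Ugt1a10, Ugt1a5 and Ugt1a2 have a single end region, the same for all, and were at −0.62 (42.3 ± 8.40 to 27.6 ± 2.76 CPM, adjusted p = 5.08e-08). Ugt1a9, Ugt1a6a and Ugt1a7c hold that region together with others and were at −0.63, −0.61 and −0.47, so these are not separate falls. Over the gene body all 6 were between −0.33 and −0.30, and Ugt1a2, Ugt1a5 and Ugt1a7c lost their calls (adjusted p = 0.0603, 0.0569 and 0.0524). In an equal make-up of cell types Ugt1a6a was at −0.40, Ugt1a7c at −0.31 and the other 4 at −0.41. Cd74, the invariant chain of antigen presentation, fell by 0.46 (adjusted p = 1.59e-04), and Gm40469, Gm3096 and Gm26802 fell by 0.57, 0.45 and 0.43. Among these, Cd74 lost its call without WT replicate 2 (adjusted p = 0.0894, range over its alternatives 1.68e-06 to 0.309), as did Zfp78 (0.178, range 6.62e-09 to 0.457). DESeq2 did not call Fnbp4 (0.250, range 4.06e-07 to 0.647) or Ugp2 (0.157, range 4.54e-08 to 0.314).

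The share of higher genes among the called was 52.4% with TMM and 35.4% with DESeq2 (301 higher, 549 lower), which changes the test and the scaling together. With total counts scaling alone it was 50.1% (199 higher, 198 lower). It was 72.7% when regions with a peak in at least 2 libraries were used (24 higher, 9 lower). In this setting Trrap (adjusted p = 0.0549, range over its alternatives 4.48e-27 to 0.0549), Itgam (0.203, range 3.76e-15 to 0.203) and Cldn4 (0.189, range 1.95e-10 to 0.189) lost their calls, as did Dnajb5 (0.240, range 2.79e-12 to 0.240) and Ugt1a10 (0.346, range 2.14e-13 to 0.346). Called genes numbered 924 higher and 503 lower without WT replicate 1, and 256 and 274 without WT replicate 2. They numbered 484 and 672 without APC-KO replicate 1, 179 and 201 without APC-KO replicate 2, and 270 and 236 without APC-KO replicate 3.

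Within single classes, SEC-PRO had 984 higher and 2757 lower regions in APC-KO and GP had 972 and 917, while PANETH had 176 and 169 and GOBLET 168 and 118. ISC had 65 and 85, EEC 13 and 14, and TUFT 2 and 18 (edgeR within each class). The classes differ in depth, with 9352 SEC-PRO cells and 1340 TUFT cells in all, and the counts per class were not compared by a test. Sums over the same number of cells in every library gave 424 and 1276 regions in SEC-PRO, 494 and 449 in GP, 92 and 82 in PANETH, and 47 and 47 in GOBLET. DESeq2 gave 784 higher and 0 lower regions in GOBLET, where edgeR gave 118 lower and DESeq2 had 8132 regions at an unadjusted p under 0.05. There DESeq2 gave an adjusted p to 6276 regions in place of 86008, so its 0 does not show that none was lower. It shared 34 of the 168 higher calls of edgeR. Without WT replicate 1 the counts were 16 and 14 in PANETH, 176 and 331 in GP, 108 and 91 in GOBLET, 596 and 578 in ISC, 43 and 30 in EEC, and 4 and 10 in TUFT. Without WT replicate 2 they were 40 and 64 in PANETH, 23 and 20 in GOBLET, 107 and 77 in GP, 484 and 795 in SEC-PRO, 6 and 33 in EEC, and 3 and 28 in TUFT. Without APC-KO replicate 1 they were 612 and 759 in PANETH, 982 and 724 in GOBLET, 933 and 1697 in GP, 109 and 166 in ISC, 6 and 19 in EEC, and 1 and 12 in TUFT. Without APC-KO replicate 2 they were 101 and 86 in PANETH, 15 and 17 in GOBLET, 557 and 338 in GP, 308 and 970 in SEC-PRO, 19 and 38 in ISC, and 7 and 11 in EEC. Without APC-KO replicate 3 they were 36 and 32 in GOBLET, 1950 and 1305 in GP, 666 and 1670 in SEC-PRO, and 33 and 68 in ISC. TUFT had 0 higher and 0 lower regions by edgeR without APC-KO replicate 2 and without APC-KO replicate 3, against 3 and 2 by DESeq2 with all libraries and 4322 and 5298 regions at an unadjusted p under 0.05.

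At gene ends within classes, GOBLET had 1103 higher and 145 lower genes and SEC-PRO 477 and 284 (edgeR). Both moved with single libraries and with DESeq2, which changes the test and the scaling together. GOBLET also moved with the scaling alone, while SEC-PRO stayed within 1.5 times the reported counts there. Total counts scaling gave 142 and 70 in GOBLET and 350 and 258 in SEC-PRO, and the replicate block 160 and 36, and 128 and 169. The same number of cells in every library gave 646 and 75, and 189 and 121. DESeq2 gave 104 and 2 in GOBLET, where it tested 1913 genes in place of 21022, and 64 and 333 in SEC-PRO. Leaving out WT replicates 1 and 2 gave 2063 and 195, and 32 and 7, in GOBLET and 1779 and 476, and 76 and 108, in SEC-PRO. Leaving out APC-KO replicates 1, 2 and 3 gave 573 and 208, 68 and 25, and 1002 and 98 in GOBLET, and 159 and 206, 89 and 116, and 1120 and 310 in SEC-PRO.

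**Figure D4:**
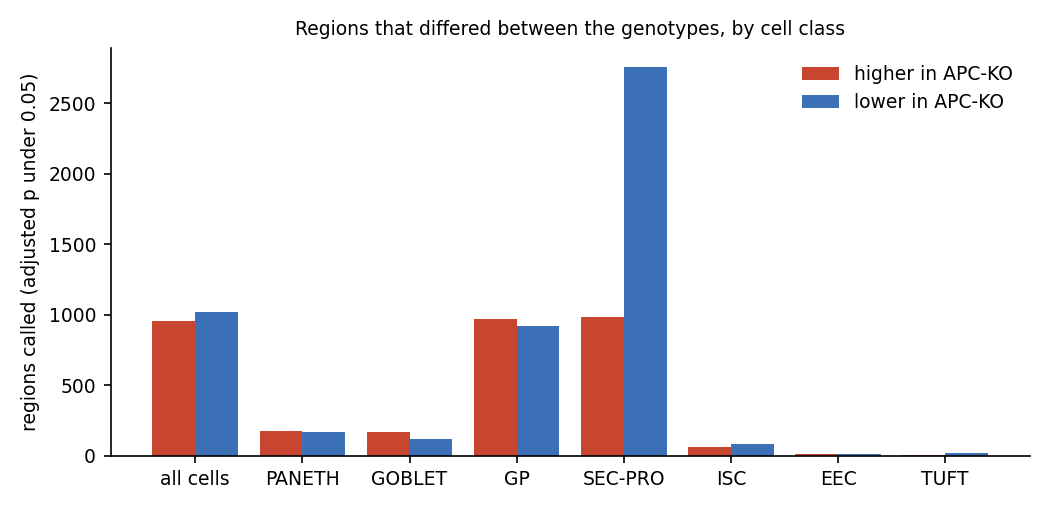
Number of regions called higher (red) and lower (blue) in APC-KO (vertical axis) in all cells and within each of the 7 classes tested. SEC-PRO has 984 higher and 2757 lower regions and TUFT 2 and 18.

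Within SEC-PRO 3 of 24 goblet genes fell and 1 rose (1 up and 6 down adjusted over the list alone), and in GP 4 fell and none rose (5 down adjusted over the list alone). By camera the goblet list was down in ISC (adjusted p = 4.61e-05), SEC-PRO (2.20e-04), GP (0.00164), EEC (0.0312) and TUFT (0.0335). The enteroendocrine list was down in GOBLET (0.00227), ISC (0.00227) and GP (0.0403), and the enterocyte list in TUFT (0.0281), and all 9 were at an adjusted p = 0.991 with an estimated correlation. The list medians were −0.04, −0.13, −0.11, −0.09 and −0.15 for goblet, −0.25, −0.09 and −0.04 for enteroendocrine and −0.11 for enterocyte. The median of all gene ends lay between 0.07 in TUFT and 0.15 in GOBLET. The goblet list lost its call in GP without APC-KO replicate 1 (adjusted p = 0.0532), in EEC without WT replicate 2 or APC-KO replicate 2 (0.393 and 0.101), and in TUFT without WT replicate 2, APC-KO replicate 1 or APC-KO replicate 2 (0.0753, 0.192 and 0.0597). The enteroendocrine list lost its call in ISC without WT replicate 1 (0.118), and in GP without any library but APC-KO replicate 1 (0.150 and 0.111 without WT replicates 1 and 2, 0.390 and 0.0892 without APC-KO replicates 2 and 3). The enterocyte list lost its call in TUFT without WT replicate 1 or APC-KO replicate 3 (0.269 and 0.0630).

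Clca1 fell in SEC-PRO (16.0 to 10.2 CPM, −0.64, adjusted p = 0.0113) and GP (−0.67, adjusted p = 0.00530). Klk1, a kallikrein, fell in SEC-PRO (−0.61, adjusted p = 0.0104), GP (17.5 to 9.92 CPM, −0.83, adjusted p = 1.11e-04) and PANETH (−0.72, adjusted p = 0.0104). Agr2, which helps fold mucins, fell in PANETH (51.6 to 33.5 CPM, −0.61, adjusted p = 1.11e-04) and GP (−0.41, adjusted p = 0.0276). The mucin gene Muc2 fell in GP (82.0 to 62.0 CPM, −0.41, adjusted p = 0.0343) and the trefoil factor gene Tff3 in SEC-PRO (−0.38, adjusted p = 0.0326). In SEC-PRO Zg16, which encodes a lectin of goblet cells, rose (0.82, adjusted p = 0.0441). These genes were named after their values were seen. In SEC-PRO Clca1 lost its call without WT replicate 2 (0.347, range over its alternatives 0.00126 to 0.347) and in GP Klk1 without WT replicate 1 (0.124, range 4.49e-05 to 0.124). Clca1 in GP lost it without WT replicate 2 or APC-KO replicate 1 (0.693 and 0.0809, range 0.00285 to 0.693), and over the gene body it was at −0.15 (0.566). Klk1 in SEC-PRO lost it without WT replicate 1 or APC-KO replicate 2 (0.162 and 0.0726, range 2.72e-04 to 0.162) and Agr2 in PANETH without APC-KO replicate 1 (0.0560, range 1.90e-05 to 0.222). Klk1 in PANETH lost its call without WT replicate 1, APC-KO replicate 2 or APC-KO replicate 3 (0.221, 0.0737 and 0.0910, range 0.00513 to 0.335). Agr2 in GP lost it without WT replicate 1, WT replicate 2, APC-KO replicate 1 or APC-KO replicate 3 (0.103, 0.218, 0.410 and 0.0619, range 0.00787 to 0.732) and over the gene body, at −0.32 (0.140). Muc2 lost it without the same libraries (0.181, 0.187, 0.348 and 0.130, range 4.69e-04 to 1.00). Tff3 lost it without WT replicate 2, APC-KO replicate 1 or APC-KO replicate 3 (0.155, 0.161 and 0.0571, range 0.00289 to 0.549) and over the gene body, at −0.084 (0.549). Zg16 lost it without WT replicate 2, APC-KO replicate 2 or APC-KO replicate 3 (0.338, 0.180 and 0.0887, range 0.0135 to 0.338).

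Itgam was higher in APC-KO in GP (17.8 to 32.1 CPM, 0.85, adjusted p = 2.76e-08), SEC-PRO (12.3 to 26.7 CPM, 1.12, adjusted p = 1.74e-07), GOBLET (0.95, adjusted p = 0.00353) and PANETH (0.57, adjusted p = 0.0109). In GP the call held in each of 11 alternatives, and in SEC-PRO it was lost with DESeq2 alone (0.0674, range over its alternatives 4.66e-14 to 0.0674). In GOBLET it was lost without WT replicate 2 (0.0790, range over its alternatives 0.00328 to 0.0790). In PANETH it was lost without WT replicate 1, APC-KO replicate 1 or APC-KO replicate 3 (0.0673, 0.0720 and 0.0544, range 0.0112 to 0.312) and over the gene body, at 0.38 (0.233). Further called members were Sis, which encodes sucrase-isomaltase, in PANETH (−1.54, adjusted p = 0.00860), and Ly6a in GOBLET (−1.18, adjusted p = 0.00380). Among Wnt targets, called members were Cd44 in GP (0.70, adjusted p = 0.00395) and Notum in SEC-PRO (0.63, adjusted p = 0.0179). Sis and Ly6a lost the call without WT replicate 2 (0.872, range 3.37e-04 to 0.872, and 0.614, range 3.69e-04 to 0.614). Cd44 lost it without WT replicate 1, WT replicate 2 or APC-KO replicate 1 (0.0570, 0.0811 and 0.224, range 0.00228 to 0.376), and over the gene body it was at 0.26 (0.376). Notum lost it without WT replicate 2, APC-KO replicate 1 or APC-KO replicate 2 (0.477, 0.0514 and 0.0574, range 2.01e-04 to 0.477). The other 10 called members were also named after their values were seen. In SEC-PRO the endocrine factor gene Neurog3 (1.27), Slc5a1 (0.68), Spi1 (0.42), Krt20 (0.40), Copz2 (0.37) and Id4 (0.34) were higher. In GOBLET Id1 was higher (0.40), and Olfm4 (−1.03), Itln1 (−0.90) and Nkx2-2 (−0.79) were lower. All 10 lost their calls without WT replicate 2 (adjusted p up to 0.545), without APC-KO replicate 2 (0.0583 to 0.258) and without at least 1 other library. Over all alternatives their adjusted p ran from 0.00136 to 0.820, the highest being Slc5a1 over the gene body (0.036).

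Peaks called in every library of one genotype and in no library of the other numbered 2112 for APC-KO and 3605 for WT, against 90449 regions with a peak in all libraries. The strongest by mean count in APC-KO lay at chromosome 6, 89643705 to 89644111, inside Txnrd3 (2936 ± 400 counts), and at chromosome 1, 172500854 to 172501585, inside Tagln2 (2887 ± 408). The next lay at chromosome 9, 62344311 to 62345277, inside Anp32a (2711 ± 162). In WT they lay at chromosome 7, 16272759 to 16273768, at Ccdc9 and Inafm1 (5743 ± 1338), and at chromosome 8, 13104580 to 13105037, inside Pcid2 (1929 ± 610). The next lay at chromosome 17, 4993812 to 4994649, inside Arid1b (1882 ± 564). Each of these 6 lay within 40 to 1368 bp of a region with a peak in the other genotype. Regions of one genotype alone were weak, with median mean counts of 153 for APC-KO and 88 for WT, against 467 for regions in all libraries. Other splits of the libraries into 2 and 3 had 272 to 3189 regions in the pair alone and 304 to 2572 in the other 3 alone. Fewer libraries make the condition easier to meet: without WT replicate 1 there were 6409 regions for APC-KO alone and 7305 for WT alone, and without WT replicate 2 there were 3627 and 11983. Without APC-KO replicates 1, 2 and 3 there were 3314 and 6177, 3010 and 5050, and 5301 and 4090.

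PANETH and GOBLET cells, both products of secretory differentiation, differed at 45003 of 87810 regions tested with the library as a block. Of these 21814 were higher in PANETH and 23189 higher in GOBLET, and 21979 differed at least 2-fold. Of 14 Paneth genes 12 were higher in PANETH and none in GOBLET, with Defa17 at 3.56, Defa24 at 2.79, the phospholipase gene Pla2g2a at 2.34 and Habp2 at 2.26 (log2, PANETH minus GOBLET). Of 24 goblet genes 16 were higher in GOBLET and 1 in PANETH, with Zg16 at −3.98 (SE 0.17, adjusted p = 3.15e-18), Clca1 at −2.96 and Muc2 at −1.14. Of 25 Wnt targets 15 were higher in PANETH and none in GOBLET, among them Axin2 at 1.73, Nkd1 at 1.62 and Lgr5 at 1.41. Over the gene body 17 Wnt targets were higher in PANETH and 2 in GOBLET. Heyl was at 2.00, and the tuft gene Ptgs1, the enterocyte gene Sis and the hormone gene Gip were higher in GOBLET, at −3.02, −2.62 and −2.58. Over the gene body Ptgs1 was at −0.81 and Clca1 at −1.41, while Zg16, Sis, Gip and Heyl were at −3.98, −2.37, −2.58 and 2.60. At these list members the genotype effect did not pass a test of its difference between PANETH and GOBLET. The WT libraries alone gave 29773 regions and the APC-KO libraries alone 40751, and 100 cells per library and class gave 5820. The classes may have been named from these counts, so the p-values are too small.

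**Figure D5:**
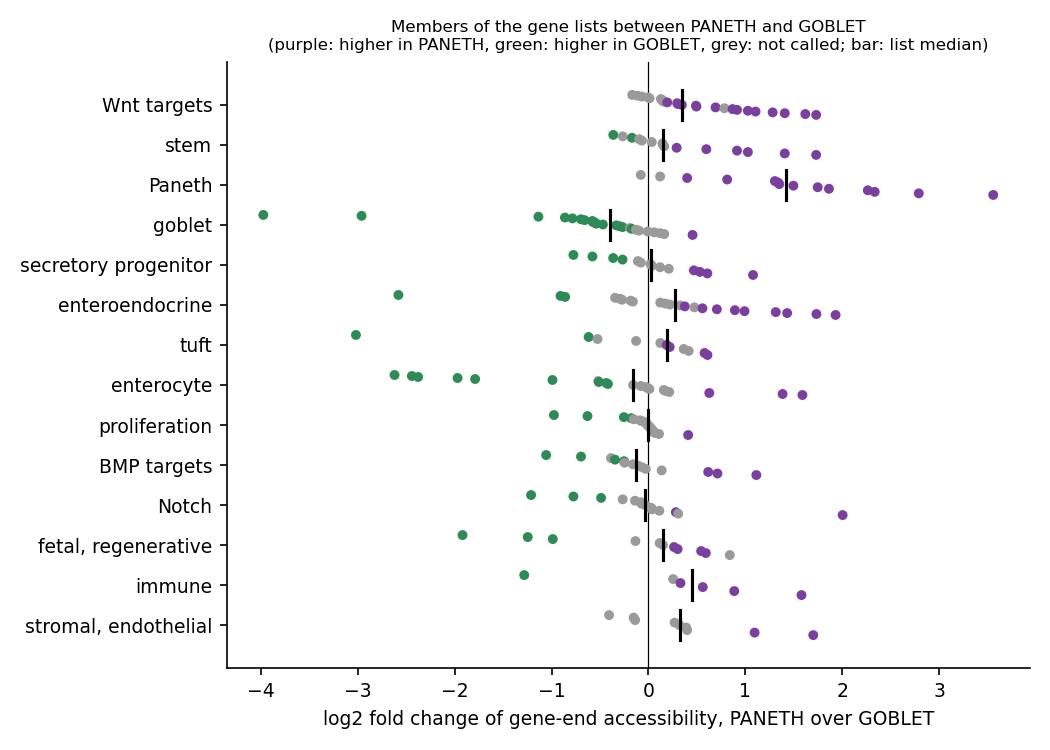
Log2 difference in accessibility at gene ends between PANETH and GOBLET cells (horizontal axis) of the members of the 14 gene lists, with called members in purple (higher in PANETH) and green (higher in GOBLET) and a bar for each list's median. Defa17 is at 3.56 and Zg16 at −3.98.

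For the remaining lists between PANETH and GOBLET, members higher in each were 6 and 2 of 15 stem genes, 4 and 4 of 14 secretory progenitor genes, 9 and 3 of 22 enteroendocrine genes, and 4 and 2 of 11 tuft genes. They were 3 and 9 of 21 enterocyte genes, 1 and 4 of 20 proliferation genes, 3 and 4 of 14 BMP targets, and 2 and 3 of 15 Notch genes. They were 4 and 3 of 11 fetal or regenerative genes, 4 and 1 of 6 immune genes, and 2 and 0 of 9 stromal or endothelial genes. Among the 21 pairs of classes the fewest regions differed between EEC and TUFT (14592) and the most between PANETH and ISC (56769). EEC and TUFT also had the fewest cells of the classes tested (2248 and 1340), and depth bears on these counts. GP and SEC-PRO differed at 31895 regions, of which 1169 reached 2-fold, and at 14356 without the library block and 75 with 100 cells per library and class.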

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

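The genotype effect on each gene and region was tested for a difference between every pair of the 7 classes. These tests were planned, and their alternatives, run for regions alone, were chosen only after the results were seen. A total of 14 of the 21 pairs had at least 1 region with such a difference, and 11 gene calls came from list members. The adjustment was made within each pair and not over the 21 pairs. For the gene calls no alternative was run and no library was left out, so how far they hold is not known. What singled these genes and regions out is a genotype effect that differed between classes in the interaction test of edgeR.

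The goblet gene Agr2 had a lower genotype effect in PANETH than in GOBLET (difference of log2 fold changes −0.55, adjusted p = 0.0260), and the endocrine transcription factor gene Nkx2-2 a higher one (0.77, adjusted p = 0.0409). Between PANETH and ISC the effect was lower for Sis (−1.64, adjusted p = 0.0269), Guca2b (−1.06, adjusted p = 0.0271) and Klk1 (−1.03, adjusted p = 0.0209), and higher for the receptor gene Kit (0.52, adjusted p = 0.0271). The genotype effect on Klk1 was also lower in GP than in ISC (−1.18, adjusted p = 0.0242) and in SEC-PRO than in ISC (−0.97, adjusted p = 0.0112). The effect was higher in GOBLET than in SEC-PRO for Tff3 (0.63, adjusted p = 0.0133). It was higher in GOBLET than in ISC for Muc2 (0.70, adjusted p = 0.0444), and higher in SEC-PRO than in ISC for Id4, which encodes an inhibitor of helix-loop-helix factors (0.53, adjusted p = 0.0407).

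Among regions, the genotype effect differed between PANETH and GOBLET at 109, with 9 higher and 100 lower in PANETH. With DESeq2 the number was 85 and with the same number of cells in every library 62. It was 27 without WT replicate 1, 43 without WT replicate 2, 788 without APC-KO replicate 1, 67 without APC-KO replicate 2 and 59 without APC-KO replicate 3. Between PANETH and SEC-PRO it differed at 157, with 85 higher and 72 lower in PANETH. With DESeq2 there were 25, with the same number of cells 71, and leaving out WT replicates 1 and 2 and APC-KO replicates 1, 2 and 3 in turn gave 76, 55, 367, 80 and 120. Between SEC-PRO and ISC it differed at 140, with 18 higher and 122 lower in SEC-PRO. DESeq2 gave 1 and the same number of cells 2, and leaving out the same libraries in turn gave 35, 0, 425, 8 and 50. The count of 0, without WT replicate 2, came from edgeR with 4700 regions at an unadjusted p under 0.05, against 1 by DESeq2 with all libraries.

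Sequences outside the standard chromosomes, which no test used, held 0.221% ± 0.00782 of the counts in APC-KO (SD, n = 3) and 0.182% ± 0.00355 in WT (SD, n = 2), with no overlap between the genotypes (exact permutation p = 0.1, the smallest that 10 splits allow).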

How the results depend on the processing

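The tests of stable peak width, of an equal make-up of cell types, of the larger gene end, of gene ends from regions with a peak in at least 2 libraries, of 100 cells per class and of removal of chromosome 18 were chosen only after the results were seen. The same holds for the alternatives for class lists, class genes and interactions, and the others were planned. With 2 WT libraries, leaving out either leaves 1, which is then assumed to vary like the APC-KO libraries. Motif tests and a correction for GC content, with and without the replicate block, were not run, because no genome sequence was used. Alternatives that vary a clustering were not run, because the classes came from the authors. For regions within a class, 15% of simulated 1.5-fold changes were recovered in PANETH, among regions at or above the median count, and other classes were not simulated. The cause of these differences was not tested, unless named.

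Without leaving out a library, 105 of 173 counts of calls stayed within 1.5 times the reported count. Direction and side of the threshold were kept by 137 of 154 list results in all cells and 43 of 54 in classes, and by 711 of 825 values of named genes in all cells, 91 of 163 in classes and 100 of 107 of named regions. With a library left out, this held for 31 of 120 counts, 56 of 70 and 32 of 45 list results, 326 of 375 and 70 of 140 gene values, 48 of 50 region values and 36 of 40 shares.

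With the replicate block, which adds the replicate number as a term, 161 genes were higher and 160 lower, and GP had 1467 higher regions. EEC had 27 higher and 33 lower regions, and TUFT 9 and 31. The Wnt target list turned to up (adjusted p = 0.874), as did the Notch list (0.874). In classes the enteroendocrine list in GP (0.151) and the enterocyte list in TUFT (0.118) were no longer called. Nothing in the labels ties a number to a shared animal or day. The deviations of libraries with the same number from their group means had correlations of −0.16 and −0.22. As the deviations of the 2 WT libraries mirror each other, these values do not decide on a pairing.

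With DESeq2, 2393 regions were higher and 2328 lower in all cells, and 301 genes were higher. Within classes it gave 347 and 265 regions in PANETH and 579 lower in GP. In GOBLET it gave 784 and 0, with an adjusted p for 6276 regions in place of 86008 (118 lower by edgeR, 8132 at an unadjusted p under 0.05). It gave 623 and 1317 in SEC-PRO, 49 lower in ISC, 9 lower in EEC and 2 lower in TUFT. DESeq2 gave 25 regions with a different effect in PANETH and SEC-PRO and 1 in SEC-PRO and ISC. In its own test Atoh1 turned to −0.043. The list tests took only its size factors, with which the proliferation and BMP lists turned to down (0.854 and 0.864). The goblet list in EEC (0.0596), the goblet list in TUFT (0.0596) and the enteroendocrine list in GP (0.124) were no longer called.

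With total counts scaling 199 genes were higher and 198 lower, the enterocyte list was called down (0.0472, but 0.886 with an estimated correlation) and the BMP list turned to down (0.932). Thinning to the smallest library turned the BMP list to down (0.908). Counting cells in place of counts gave 306 higher genes. With gene bodies the Wnt, BMP and fetal or regenerative lists changed direction (each 1.00), the enterocyte list was called down (0.0261, but 1.00 with an estimated correlation) and Slc5a1 turned to −0.064. In classes the enteroendocrine list in GOBLET (0.254), the enteroendocrine list in GP (0.192) and the goblet list in TUFT (0.122) were no longer called.

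With regions that have a peak in at least 2 libraries, 123 were lower, and 24 genes were higher and 9 lower. The Paneth list was not called (0.536), the immune list turned to down (0.861) and Vim to 0.19. Here a library without a peak counts as 0, which widens the spread between libraries of one group. With an equal make-up of cell types, 1705 regions were lower, the Paneth and tuft lists were not called (0.718 and 0.0746) and the goblet list was called down (3.69e-04, but 0.985 with an estimated correlation). The Notch list turned to up (0.948), Atoh1 turned to −0.019 and Sox18 to 0.053. Without chromosome 18, TUFT had 1 higher region.

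The same number of cells in every library, which lowers the depth, gave 92 higher and 82 lower regions in PANETH, 47 and 47 in GOBLET, and 494 and 449 in GP. It gave 424 and 1276 in SEC-PRO, 29 and 55 in ISC and 8 lower in TUFT. The enteroendocrine list in GP (0.0627), the enterocyte list in TUFT (0.0550) and the goblet list in TUFT (0.289) were no longer called. Effects differed at 62, 71 and 2 regions in PANETH and GOBLET, PANETH and SEC-PRO, and SEC-PRO and ISC. With 100 cells per class PANETH and GOBLET differed at 5820 regions. Stricter peaks gave 1303 regions in APC-KO alone and 2007 in WT alone.

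Leaving out each library in turn gave these ranges. Regions were 185 to 2246 higher and 144 to 2511 lower, and genes 179 to 924 higher and 201 to 672 lower. By class, regions higher and lower were 16 to 612 and 14 to 759 in PANETH, 15 to 982 and 17 to 724 in GOBLET, and 107 to 1950 and 77 to 1697 in GP. They were 308 to 1344 and 795 to 3135 in SEC-PRO, 19 to 596 and 38 to 578 in ISC, 6 to 43 and 11 to 33 in EEC, and 0 to 4 and 0 to 28 in TUFT. The 0 in TUFT came without APC-KO replicate 2 or 3 by edgeR, with 4322 and 5298 regions at an unadjusted p under 0.05, and DESeq2 called 3 and 2 with all libraries. Regions with different effects were 27 to 788 for PANETH and GOBLET, 55 to 367 for PANETH and SEC-PRO and 0 to 425 for SEC-PRO and ISC, the 0 without WT replicate 2 by edgeR. In that setting 4700 regions had an unadjusted p under 0.05, and DESeq2 called 1 with all libraries. Peaks in one genotype alone were 3010 to 6409 for APC-KO and 4090 to 11983 for WT.

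For list tests in all cells the adjusted p ran from 0.200 to 0.999 for Wnt targets, 0.200 to 0.919 for stem, 2.63e-07 to 0.0515 for Paneth, and 0.0669 to 0.810 for goblet. It ran from 0.645 to 0.936 for secretory progenitor, 7.25e-04 to 0.837 for enterocyte, 0.743 to 0.999 for proliferation, 0.582 to 0.999 for BMP and 0.200 to 0.934 for Notch. In classes it ran from 0.00272 to 0.393 for goblet in EEC, 4.16e-04 to 0.0532 for goblet in GP, and 0.00292 to 0.192 for goblet in TUFT. It ran from 0.0119 to 0.390 for enteroendocrine in GP, 0.00292 to 0.118 for enteroendocrine in ISC and 0.00575 to 0.269 for enterocyte in TUFT. The difference in share ran from −1.35 to 4.18 points for GOBLET, −3.66 to 4.87 for GP and −12.5 to 2.05 for ISC. Log2 fold changes that changed sign ran from −0.92 to 0.13 for Anxa10, −0.024 to 0.13 for Atoh1, −1.33 to 0.054 for Ly6a, −0.028 to 0.28 for Slc12a2, −0.29 to 0.17 for Sox18 and −0.42 to 0.19 for Twist1.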

Other observations

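The tests of cell make-up, of DNA near Apc and of other splits of the libraries were chosen only after the results were seen, while those of neighbouring regions, of goblet-specific regions within classes and of the SEC-PRO axis were chosen before their results were seen.

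Beyond the comparison of genotypes, each class was compared with the mean of the other classes. In EEC, 21 of 22 enteroendocrine genes were higher than in the other classes, with the transcription factor genes Neurod1 at 3.86 and Neurog3 at 2.76 (log2 over the other classes). In TUFT, 11 of 12 tuft genes were higher, with Alox5ap at 3.53 and Avil at 2.93. In ISC, 15 of 21 enterocyte genes were higher, among them the digestive enzyme gene Mgam at 3.12 and the fatty acid binding gene Fabp1 at 2.53, next to the stem cell gene Olfm4 at 1.68, and 5 of 15 stem genes were higher. SEC-PRO had 17 of 24 goblet genes and 13 of 20 proliferation genes higher, with Fcgbp at 0.62 and Agr2 at 0.52. GP had 14 of 24 goblet genes higher, with Zg16 at 1.26 and Muc2 at 1.13, and 17 of 20 proliferation genes lower. In EEC the Wnt target Axin2 was at 2.23.

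Among the regions with the largest differences between the genotypes, 531 were called and changed at least 2-fold. With an equal make-up of cell types the median ratio of their log2 fold changes to those in all cells was 0.865 (interquartile range 0.720 to 0.981). This argues against different numbers of cells per class as the whole of the difference, while counts per cell were not made equal. A share of 16.6% of the 531 had another such region of the same direction within 100 kb, against a median of 4.90% and a maximum of 9.23% over 1000 random draws. Runs include 8 lower ones on chromosome Y from 90739811 to 90809316, 3 lower ones at Alox5ap and 3 lower ones at Mid1 on chromosome X from 169978789 to 169994766. Stretches of DNA that differ between the mouse lines, in sequence or copy number, may account for part of them. The draws took regions at random places, so neighbouring regions of one gene that change together would exceed them too, and the comparison singles out no cause. Alox5ap is also a gene of TUFT cells (3.53 over the other classes), whose share was lower in APC-KO. Its gene end kept its call with an equal make-up, so cell numbers alone may not account for its run. As counts per cell were not made equal, make-up stays open for a part of it. In the 20 Mb around Apc 4.01% of 674 regions were called, against 2.19% genome-wide, which is percentile 94.7 of 455 windows. DNA carried along with the floxed allele stays open, as does an effect of the loss of Apc itself. The runs on Y and X lie in or beside the pseudoautosomal region, which both chromosomes carry, so they need not follow the sex of the animals. A different sex was not tested and stays open. Chromosome X held 1.42% ± 0.00422 of counts in WT and 1.39% ± 0.00814 in APC-KO, which does not decide on it, since the inactive X of a female is largely closed. Chromosome Y held 0.0321% ± 0.00811 in WT (0.0264% to 0.0378%) and 0.0110% ± 0.00384 in APC-KO (0.00853% to 0.0154%), without overlap. This share includes the lower run near the end of Y and was not split from it, so it leaves the sex open too.

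The higher Paneth list and the lower enteroendocrine and tuft lists in all cells were set against a different make-up of the sorted cells. The equal make-up evened the numbers of cells, not their counts. Median counts per PANETH cell were 9065 and 12873 in WT and 16663, 11869 and 13088 in APC-KO. In each library these lay below the median of all kept cells in WT and above it in APC-KO. A difference in make-up by counts can therefore remain. For the Paneth list the median less that of all genes went from 0.20 to 0.06 with an equal make-up, a ratio of 0.312, so a larger share of PANETH cells may account for most of it, though Defa24 kept its call (0.69, adjusted p = 0.00844). For the enteroendocrine list it went from −0.18 to −0.21, a ratio of 1.14, so the middle of the list did not shrink. The lower quartile of its log2 fold changes went from −0.37 to −0.24. The ratio thus does not decide on make-up for the members that fell most. The called members Isl1 and Pax6 of this list went from −0.52 each to −0.35 and lost their calls (adjusted p = 0.117 and 0.193), so a part of those falls stays open to make-up. For the tuft list it went from −0.21 to −0.15, a ratio of 0.712, and the few members leave make-up open there. Within their own classes camera called none of the 3 lists (adjusted p = 0.995 in PANETH, 0.106 in EEC and 0.359 in TUFT). The list medians were 0.10, 0.015 and −0.11, against 0.08, 0.11 and 0.07 for all gene ends of the class. No member was called there over all genes. A change within these cells on loss of Apc that the tests could not detect stays open.

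The lower goblet list within ISC, SEC-PRO and GP was set against fewer goblet-type cells or free DNA inside those classes, which would lower regions specific to GOBLET. In ISC the median log2 fold change over 3164 regions at least 4-fold higher in GOBLET was −0.39 (from −0.68 without WT replicate 1 to −0.12 without WT replicate 2), and in GP it was −0.18 over 126 regions (−0.25 to −0.12), as that explanation would have it. In SEC-PRO it was −0.0080 over 490 regions (−0.10 to 0.09), which neither shows nor excludes it. A candidate explanation in ISC and GP is thus a different mixture of cells under one class name, and a lower accessibility of goblet genes in single cells without Apc stays open in all 3 classes.

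A hypothesis was that SEC-PRO cells without Apc move from GOBLET towards PANETH accessibility. Of the regions lower in APC-KO in SEC-PRO, 54.1% were higher in GOBLET and 17.4% in PANETH, and of those higher in APC-KO 30.4% and 31.4%, where all tested regions had 26.4% and 24.7%. Across all regions, which are not independent, the correlation of the genotype effect in SEC-PRO with the difference of PANETH and GOBLET was 0.0844. Among the other 9 of 10 splits of the libraries, WT replicate 2 paired with APC-KO replicate 1 or 2 gave more (0.103 and 0.102). Every pair of a WT and an APC-KO library holds the same part of the genotype effect. WT replicate 2 paired with APC-KO replicate 3 gave 0.066. WT replicate 1 paired with APC-KO replicates 1, 2 and 3 gave −0.037, −0.049 and −0.079. In these pairs the sign thus went with the WT replicate. The prediction, a correlation larger in size for the real split than for each other split, was not met. As 10 splits allow no p under 0.1, this does not exclude the hypothesis, which stays open. The 54.1% goes with a move away from GOBLET, while regions higher in APC-KO leaned to neither class. Against such a move, the 490 regions at least 4-fold higher in GOBLET than in SEC-PRO did not fall in SEC-PRO relative to other regions. Their median log2 fold change was −0.0080, against −0.0086 for all regions.

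The real split of the libraries called 1977 regions and the highest of the other 9 of 10 splits called 22. For genes these counts were 929 and 160. Each was reached in 1 of the 10 splits, which are too few for a share under 0.05.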
